A study of Mus musculus with 8 samples.

How the data were processed

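The series holds RNA-seq of 8 single mouse oocytes arrested at metaphase of the second meiotic division (MII), 4 Hira f/f oocytes without Cre in their genotype label, called WT, and 4 Hira f/f oocytes with Gdf9-Cre, called KO, per the labels. The labels do not wholly match on this, since the titles of all 8 samples, WT included, carry the tag Gdf9-Cre+, and the groups follow the genotype and description labels. Per the labels' protocols, cDNA was made and amplified directly from each oocyte with a SMARTer ultra-low-input kit, a fixed amount of ERCC spike-in RNA was added to every reaction, and sonicated cDNA was made into libraries sequenced on an Illumina HiSeq instrument.

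The values are FPKM, fragments per kilobase of gene scaled to the library total, as deposited by the authors in 1 table of 37620 Ensembl gene identifiers. The submitters' processing notes name Bowtie 0.12.8, TopHat2 2.0.2, Bowtie2, HTSeq, edgeR 3.1.10 and genome build mm9, without a role for each. The annotation release, the gene lengths and the use of strand in counting are not given in the sources used here. No ERCC values were used here, so amounts of RNA per oocyte were not measured and all levels are relative within a library. Symbols came from a gene name table that matched 32897 identifiers. Biotypes, exon overlaps and coordinates came from GENCODE M21 on GRCm38, and no coordinates were carried between builds.

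FPKM of a gene moved in steps of 1 read, which gave whole reads and library totals back from the deposited FPKM. Of the values above 0, 100.0% were whole within 0.0001 reads. Library totals rested on the 4606 genes, of 10879 usable ones, whose exon length equals that in GENCODE M21. What the totals count besides reads in listed genes is not given in the sources used here. Because FPKM is divided by this total, a library with a smaller part of its reads in listed genes has lower FPKM for the same share of gene reads.

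Each sample is 1 cell and the labels name no female, so it is not known whether the 4 oocytes of a genotype came from 1 female or several. Each genotype was therefore counted as 1 sample with no replicate, and no test between genotypes is reported. The tests planned before the data were examined, limma on log2(FPKM + 1), camera on gene lists and exact permutations over oocytes, treated oocytes as replicates. They were run and then set aside for this reason, and their p-values and counts of genes are not given. The matched percentiles, the counts of genes that differ by 2-fold in mean FPKM and the antisense tests in the closing section were chosen after those results had been seen. SDs below describe spread between oocytes, which mixes differences between cells, females and library preparations, and a difference that exceeds it cannot be assigned to the genotype.

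A gene was compared if its FPKM was at least 1 in at least 4 of the 8 oocytes, which held for 7833 genes. Differences are KO minus WT means of log2(FPKM + 1), a scale that understates changes of low genes, and folds are ratios of mean FPKM. Where a genotype had no read, a fold was taken against 3 reads per library and is a lower bound that covers counting error only, as reads amplified by PCR are not independent molecules. Setting such genes to 3 reads per library left the median of each list as it was. Of 20 gene lists fixed before the data were examined, 17 had at least 3 compared members, and their median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile was taken anew under each alternative, among lists drawn from the genes of that alternative. It describes these libraries, treats the members of a list as independent, and is not a test across females. The lists cover the HIRA complex, other histone chaperones, histones, DNA and histone methylation enzymes, oocyte and maternal-effect genes, meiosis, maternal mRNA, DNA damage, 2-cell-stage, Hox, olfactory receptor and imprinted genes, ribosomal, respiratory, mitochondrially encoded and proteasome genes, and 3 sets of markers of other cells. In simulated lists of 20 genes within the 7833 compared, 20 of 20 lists shifted by 1 on the log2 scale lay above percentile 97.5. Outside percentiles 2.5 to 97.5 lay 1 of 20 unshifted lists. The unshifted lists were random draws from the same genes as the matched lists. The check therefore does not cover lists whose members vary together, and shifts smaller than 1 were not simulated.

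Genes named in the text follow a rule fixed before the data were examined. It takes the HIRA complex list, the 12 largest differences in each direction among genes with adjusted p under 0.05 in the limma fit and no overlap between genotypes, up to 4 members per list with the smallest unadjusted p, and for other cells up to 4 members with the highest mean FPKM. The fit served only to choose names. Alternatives covered the pseudocount, filters, scaling, weights, leaving out each oocyte, and a replicate block. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.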

Results

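The transcriptomes of 8 single MII oocytes were compared to ask how the RNA of the mature egg differs when Hira is deleted by Gdf9-Cre, a recombinase expressed in oocytes. Hira encodes a histone chaperone that deposits the histone variant H3.3 outside DNA replication. Library totals lay between 38032455 and 50208686 reads, and 31335729 to 42421000 reads per library fell in listed genes. Each genotype counts as 1 sample, because the labels name no female for any oocyte. The differences below describe these oocytes and carry no test.

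Hira (ENSMUSG00000022702, chromosome 16, 18877037 to 18970309 on the plus strand of GRCm38) was near the detection limit in both genotypes. The WT oocytes numbered 1, 2, 4 and 5 held 42, 0, 96 and 1 reads, and the KO oocytes numbered 1, 3, 5 and 6 held 0, 2, 0 and 2 reads. The sums were 139 and 4 reads, in the direction of the labels, and the difference was -0.17 on the log2(FPKM + 1) scale. As 2 of the WT oocytes also had at most 1 read, Hira is a weak check of single labels. GENCODE M21 places 44.7% of its exonic bases within Gm28539 as well.

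KO oocytes had more genes detected and a smaller part of their library in listed genes. FPKM of at least 1 was reached by 7324 ± 168 genes in WT and 8197 ± 282 in KO (SD, n = 4 oocytes each), with no overlap between 7121 to 7467 and 7827 to 8512. Listed genes held 84.9% ± 0.862 of the library total in WT and 78.1% ± 2.63 in KO. The 10 most abundant genes took 11.7% ± 1.02 of gene reads in WT and 8.77% ± 0.356 in KO. Spread between oocytes was measured as the median SD over genes of log2(FPKM + 1), which was 0.41 in WT and 0.38 in KO, and the order of these values turned without WT oocyte 1.

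**Figure D1:**
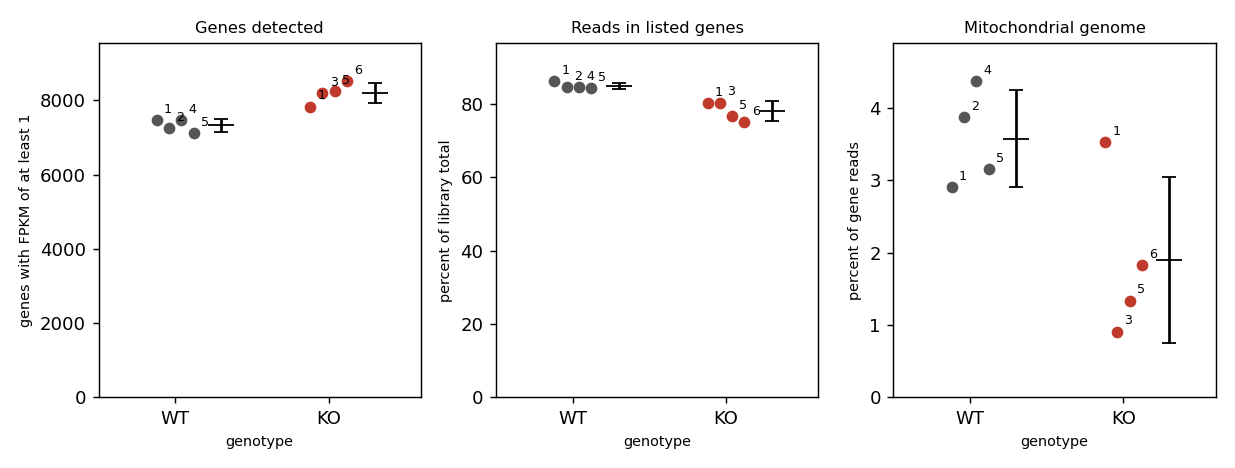
Genes with FPKM of at least 1, percent of the library total in listed genes and percent of gene reads from the mitochondrial genome, with 1 numbered point per oocyte and mean ± SD to the right of each genotype. All KO oocytes lie above all WT oocytes for detected genes and below them for reads in listed genes, while KO oocyte 1 lies among the WT oocytes for mitochondrial reads.

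Among the 12 named genes with the largest differences towards KO, WT means lay between 0 and 16.8 FPKM. Mpv17l, which encodes a peroxisomal and mitochondrial protein, averaged 16.8 ± 6.84 FPKM in WT and 405.7 ± 147 in KO, a 24.2-fold difference in means. Tapbpl, which encodes the peptide editor TAPBPR of antigen presentation, was 19.2-fold higher in KO, and Efna1, encoding the Eph receptor ligand ephrin-A1, 16.5-fold higher. Hes1, a transcriptional repressor downstream of Notch, had 0.302 ± 0.336 FPKM in WT and 19.5 ± 1.48 in KO, 64.8-fold higher and 131.9-fold without WT oocyte 4. Olfr1340, an olfactory receptor gene, had 1 read over the WT oocytes and 4152 over the KO oocytes. The microRNA gene Mir146, counted as reads over the gene and not as mature microRNA, had no read in WT and was at least 29.5-fold higher in KO, or at least 18.98-fold without KO oocyte 5. Mir3473a had 2 reads in WT and 1075 in KO, of which 83.3% were in KO oocyte 1 and 179 in the others. Cox4i2, a cytochrome c oxidase subunit isoform, was 47.6-fold higher and 294.7-fold without WT oocyte 5, and its log2 difference of 4.36 was 2.29 with a replicate block. The lincRNA gene B230312C02Rik was 67.2-fold higher, and Gm16086 was 42.2-fold higher and 87.4-fold without WT oocyte 5. ENSMUSG00000092003 and ENSMUSG00000086627, which have no symbol in the name table, were 17.2-fold and 13.4-fold higher.

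The 12 named genes with the largest differences towards WT had WT means between 5.74 and 168.7 FPKM. Tcl1b5, of the Tcl1 family, averaged 98.5 ± 31.3 FPKM in WT and 7.78 ± 4.44 in KO, and Ugcg, glucosylceramide synthase, 138.1 ± 24.9 and 24.4 ± 3.80. Cth, the cystathionine gamma-lyase of cysteine synthesis, was 6.09-fold lower in KO and 10.5-fold without KO oocyte 5. KO oocyte 1 held most KO reads of 3 genes. Tuba3b, an alpha-tubulin, was 50.5-fold lower with it and 375.7-fold without it. The other KO oocytes held 0.0128 to 0.0357 FPKM of Tuba3b, below the mean of 0.0391 FPKM that 3 reads per library give in KO. Its larger fold therefore rests on few reads. Tmem74 was 9.47-fold lower with KO oocyte 1 and 27.7-fold without it, and S100a14 15.4-fold and 72.9-fold. Mllt11 was 8.03-fold lower, and the ESCRT-III gene Chmp2a 7.81-fold and 11.8-fold without KO oocyte 6. The lincRNA gene Gm12670 averaged 33.1 FPKM in WT and 2.37 in KO, and was 84.7-fold lower without KO oocyte 5. ENSMUSG00000079437 was 10.5-fold lower and 137.5-fold without KO oocyte 3. The other KO oocytes held 0 to 0.107 FPKM of it, where 3 reads per library give a mean of 0.0818, so the larger fold rests on few reads. The immunoglobulin segment Igkv8-26 had 377 reads in WT and 26 in KO, all of the latter in KO oocyte 6.

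**Figure D2:**
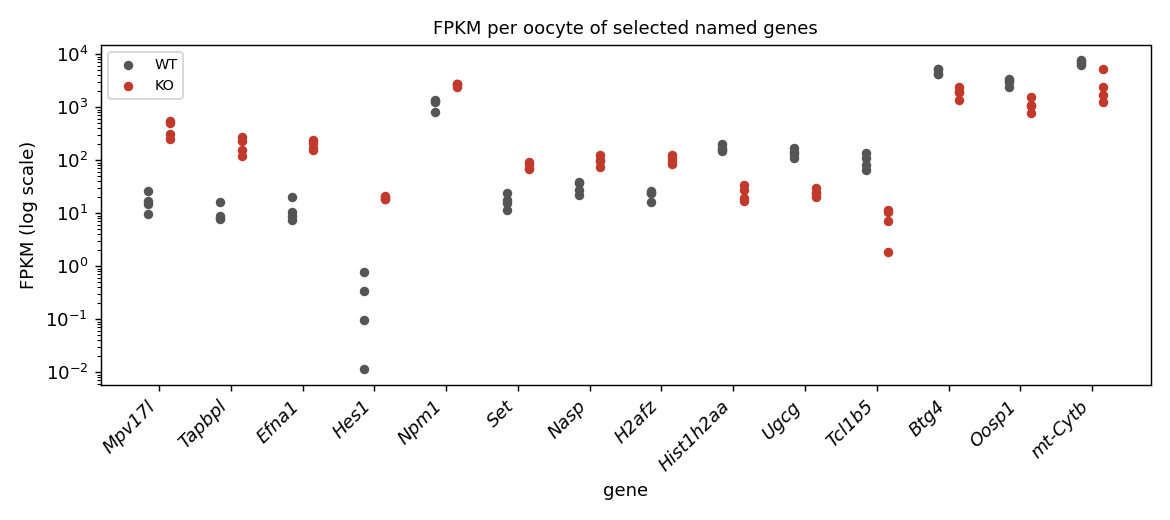
FPKM on a log scale of 14 named genes, with 1 point per oocyte, WT in grey and KO in red. Mpv17l, Tapbpl, Efna1 and Hes1 are higher in all KO oocytes, and Hist1h2aa, Ugcg and Tcl1b5 lower. The naming rule required no overlap between genotypes for these genes, so their separation follows from the choice.

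The partners of HIRA stayed within 2-fold. None of the 6 compared members of the HIRA complex and H3.3 list differed by 2-fold or more, and their median difference of 0.27 lay at percentile 81.8 of matched lists, and was 0.17 with median-of-ratios scaling and 0.42 with a replicate block. H3f3b, the more abundant H3.3 gene, averaged 1618 ± 166 FPKM in WT and 1843 ± 86.9 in KO, and H3f3a 35.9 ± 14.4 and 53.3 ± 16.0. Asf1a, a chaperone that hands H3.3 to HIRA, had 43.3 ± 5.78 and 62.4 ± 5.82 FPKM. The differences were 0.36 for Ubn1, -0.06 for Ubn2, which turned to 0.04 when scaled by the share of reads in genes, and -0.35 for Cabin1.

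Other histone genes and chaperones differed in both directions. Over all 7054 compared protein-coding genes, 16.8% were at least 2-fold higher in KO and 6.49% at least 2-fold lower. These shares are the background for the 2-fold counts of each list. Among 20 other chaperones 3 were at least 2-fold higher in KO and none was 2-fold lower. Set was 4.61-fold, Nasp, a carrier of soluble histone H3, 3.20-fold and nucleophosmin, Npm1, 2.27-fold higher. The mean of the chaperone list was 0.14, while its median of -0.08 lay at percentile 34.6 and turned to 0.02 when scaled by the share of reads in genes. The median was -0.18 with median-of-ratios scaling, -0.15 without KO oocyte 3 and -0.0016 without WT oocyte 1. Mcm2 had a difference of -0.66. Of 11 compared histone genes, 2 were at least 2-fold higher and 4 at least 2-fold lower, with a median of -0.25 at percentile 7.23. The median had another sign in 7 of 19 alternatives and ranged from -0.56 without KO oocyte 1 to 0.29 without WT oocyte 1, and it lay below the central 95% of matched lists without KO oocyte 1, without KO oocyte 3 and with array weights. H2afz, encoding the variant H2A.Z, was 4.58-fold higher. Hist1h2aa was 6.91-fold lower and Hist1h2bc 4.67-fold lower, or 7.69-fold without KO oocyte 6, and Hist1h2bj had 249 reads over the WT oocytes and none in KO; 33.1% of the exonic bases of Hist1h2aa are shared with another gene. Near-identical copies and pseudogenes of histone, Npm1, Set and H2afz sequences make these values uncertain, as the treatment of shared reads is not given in the sources used here.

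Single chromatin enzymes differed while their list medians stayed within the central 95% of matched lists. Of 15 DNA methylation genes, 2 were at least 2-fold higher in KO and 1 at least 2-fold lower. Of 28 histone methylation enzymes, 2 were at least 2-fold higher and 0 at least 2-fold lower. The shares over all protein-coding genes were 16.8% and 6.49%, so these counts do not set the 2 lists apart. Among 15 DNA methylation genes, Kdm1b, an H3K4 demethylase needed for maternal imprints, was 2.36-fold and the de novo methyltransferase Dnmt3a 2.78-fold higher in KO, and Trim28 was 1.70-fold higher. Dppa3, a maternal protector of DNA methylation, averaged 11910 ± 2412 FPKM in WT and 7077 ± 934 in KO, and its log2 difference of -0.74 was -0.12 with cyclic loess normalization. Dppa3 had rank 1 in all 8 oocytes, so quantile normalization makes its values equal by construction and shows nothing on it. The list median of 0.21 lay at percentile 84.5, and was 0.048 without KO oocyte 6 and 0.02 with cyclic loess normalization. Among 28 histone methylation enzymes the median was -0.09, at percentile 12.4, ranging from -0.24 with quantile normalization to 0.044 without WT oocyte 4, while Pcgf6, a Polycomb subunit, was 2.01-fold higher, with differences of -0.47 for Eed, 0.58 for Cxxc1 and -0.51 for Nsd2.

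Oocyte and maternal-effect genes had a median that depended on the alternative. The median difference of the 45 compared members was -0.11, at percentile 47.5 of matched lists. It turned to 0.01 when scaled by the share of reads in genes and was -0.25 without WT oocyte 2, at percentile 5.72. The percentile was 4.38 with array weights, 4.36 with voom and 4.19 without KO oocyte 6. With a replicate block, which rests on oocytes 1 and 5 of each genotype, the median was -0.40. This lay at percentile 0.195 and below the matched range of -0.31 to 0.11. Of these genes 3 were at least 2-fold higher and 3 at least 2-fold lower in KO. Oosp1, an oocyte-secreted protein gene, averaged 3019 ± 482 FPKM in WT and 1118 ± 313 in KO. Rfpl4 and the homeobox gene Obox5 were 2.02-fold and 1.82-fold lower, and Nlrp9b was 2.16-fold higher. Of 39 maternal mRNA storage and decay genes 5 were at least 2-fold higher and 2 lower, with a median of 0.05 at percentile 56.9 that had another sign in 8 of 19 alternatives, from -0.07 with quantile normalization to 0.15 when scaled by the share of reads in genes, with -0.049 without WT oocyte 5 and 0.12 without WT oocyte 4. Btg4, the adaptor that recruits the CCR4-NOT deadenylase in maternal mRNA decay, was 2.49-fold lower and Pabpn1l, a partner in that decay, 3.54-fold lower. Sympk, a scaffold of the polyadenylation machinery, was 6.55-fold and the RNA helicase Ddx6 4.15-fold higher.

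Meiotic, damage-response and proteasome genes stayed within the central 95% of matched lists in all 19 alternatives that could move them. None of 39 meiotic genes differed by 2-fold, with a median of -0.09 at percentile 33.4 that ranged from -0.20 with median-of-ratios scaling to 0.03 with a replicate block and lay between -0.14 without WT oocyte 5 and -0.042 without WT oocyte 4. Cks2, a cyclin-dependent kinase subunit, was 1.89-fold higher, the separase gene Espl1 1.80-fold and Ube2c 1.95-fold, the last with overlap between genotypes. The kinase gene Aurkc averaged 628.5 ± 96.2 FPKM in WT and 1004 ± 318 in KO. Among 26 damage-response genes 3 were higher and 1 lower by at least 2-fold, with a median of 0.02 at percentile 23.6 that had another sign in 7 of 19 alternatives, from -0.10 with median-of-ratios scaling to 0.14 when scaled by the share of reads in genes, with -0.012 without WT oocyte 1 and 0.038 without KO oocyte 5. Nbn was 2.15-fold higher and the differences of Cdkn1a, Gadd45a and Trp63 were 1.02, -0.64 and 0.56. The 33 proteasome genes had a median of 0.09 at percentile 71.7 that ranged from -0.03 with median-of-ratios scaling to 0.21 when scaled by the share of reads in genes and lay between 0.029 without KO oocyte 3 and 0.17 without WT oocyte 1, with differences of -0.60 for Psmb3, -0.88 for Psmd11, 0.75 for Psmd10 and 0.66 for Psmb2. The 73 ribosomal protein genes had a median of 0.07 at percentile 46.5 that had another sign in 5 of 19 alternatives, from -0.19 without KO oocyte 6, below the central 95% of matched lists, to 0.17 when scaled by the share of reads in genes, with 0.15 without WT oocyte 4. Rps25 was 3.17-fold higher and Rps16, Rps15a and Rps3a1 were 2.01-fold, 2.05-fold and 3.50-fold lower, Rps3a1 with overlap between genotypes.

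Respiratory chain genes of the 2 genomes lay on opposite sides. All 12 compared mitochondrially encoded genes had lower means in KO, 9 of them by at least 2-fold, and their median of -1.63 lay below all 10000 matched lists. These genes come from 1 genome and can vary together, while matched lists draw genes independently, so that rank does not measure chance. The median was -0.93 with a replicate block, -1.17 with cyclic loess normalization and -2.11 without KO oocyte 1, each below the central 95% of matched lists. The mitochondrial genome held 3.58% ± 0.667 of gene reads in WT and 1.90% ± 1.15 in KO, and KO oocyte 1, at 3.52%, lay among the WT oocytes. mt-Cytb, mt-Nd5, mt-Atp8 and mt-Nd2 were 2.68-fold, 2.73-fold, 2.86-fold and 2.98-fold lower, mt-Nd5 with overlap between genotypes, and 4.03-fold, 4.50-fold, 5.39-fold and 5.37-fold lower without KO oocyte 1. The 66 nuclear-encoded genes had a median of 0.36, at percentile 99.8, with 14 at least 2-fold higher and 3 lower, and the median ranged from 0.088 with a replicate block to 0.55 with voom. It lay above the central 95% of matched lists in 15 of 19 alternatives, and within it with a replicate block, with a pseudocount of 5 (0.15), without KO oocyte 6 (0.21) and without WT oocyte 1 (0.26). Ndufs8, a complex I subunit, had no WT read and was at least 67.6-fold higher, and Ndufb11, Cox4i1 and Uqcrq were 2.07-fold, 2.28-fold and 2.02-fold higher.

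The olfactory receptor genes that passed the filter were higher in KO as a list. Of these 17 genes 12 were at least 2-fold higher and 2 lower, with a median of 1.04 at percentile 99.98. The median was 2.63 with voom and 0.47 with a pseudocount of 5, and with no filter, over the 86 olfactory receptor genes with any read, it was 0.14. It lay above the central 95% of matched lists in 18 of 19 alternatives, and at percentile 92.5 for the 6 genes with a mean FPKM of at least 5. Of the 17 genes, 2.0 passed the filter by the KO oocytes alone and 0.0 by the WT oocytes alone, against 163.0 and 27.0 of 7833 compared genes. Reads outside listed genes, 15.1% ± 0.862 of the library total in WT and 21.9% ± 2.63 in KO, were higher in the same KO oocytes. What this remainder counts, ERCC reads included or not, is not given in the sources used here. Its relation to the olfactory receptor genes was not tested. Olfr420 had no WT read and was at least 29.7-fold higher, Olfr877 was 9.72-fold higher, 22.8-fold without WT oocyte 1 and 6.22-fold without KO oocyte 6, and Olfr288, with 69.1% of its exonic bases shared, 9.56-fold lower. The 7 compared 2-cell-stage genes had a median of 0.34 at percentile 84.4, and 0.14 without KO oocyte 6. With no filter 23 such genes had a median of 0.51, above the central 95% of matched lists. Gm2016 averaged 1.15 ± 0.777 FPKM in WT and 21.8 ± 7.84 in KO, and Zscan4d, 1 of several near-identical copies, was 23.5-fold higher with overlap between genotypes, while Sp110 and Zfp750 had differences of 0.34 and -0.51. The median of imprinted genes was 0.06 with no filter and 0.39 without WT oocyte 2. Among 14 imprinted genes, with a median of 0.24 at percentile 65.3 that ranged from -0.04 with quantile normalization to 0.82 at percentile 98.4 for the 6 with a mean FPKM of at least 5, the neighbours Igf2r and Slc22a3 were 2.64-fold and 2.99-fold higher. Airn was 14.9-fold higher and 144.7-fold without WT oocyte 5, which held most of its WT reads. The larger fold rests on 0.0616 FPKM in WT oocyte 2, with no read in WT oocytes 1 and 4. Mest had a difference of -0.90. Airn is antisense to Igf2r, and its value is uncertain because the use of strand in counting is not given in the sources used here. Hoxa7 was the 1 Hox gene compared, with a difference of -0.37.

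Few markers of other cells were detected in either genotype. Of 68 such markers, 6.00 ± 1.83 reached FPKM of at least 1 in WT and 6.50 ± 1.73 in KO. The granulosa genes Cyp19a1, Nr5a2 and Kitl had differences of -0.11, 1.02 and 0.53, all within overlapping ranges, with Cyp19a1 at 21.5 ± 4.54 and 21.8 ± 9.75 FPKM, and their median of 0.53 lay at percentile 77.6, between 0.19 without WT oocyte 1 and 0.89 without WT oocyte 4, and was 0.0027 over 19 markers with no filter and 1.58 with voom. The difference of Cyp19a1 turned to 0.30 without KO oocyte 1, to 0.01 without WT oocyte 5, to 0.10 with array weights and to 0.0067 when scaled by the share of reads in genes. Cd68, the 1 immune marker compared, had a difference of 0.33, which turned to -0.02 with a replicate block and to -0.0051 with cyclic loess normalization. Cdh1, which encodes E-cadherin, averaged 21.3 ± 4.64 FPKM in WT and 38.5 ± 10.2 in KO, 1.81-fold higher, and the endothelial marker Pecam1 5.35-fold lower in KO.

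**Figure D3:**
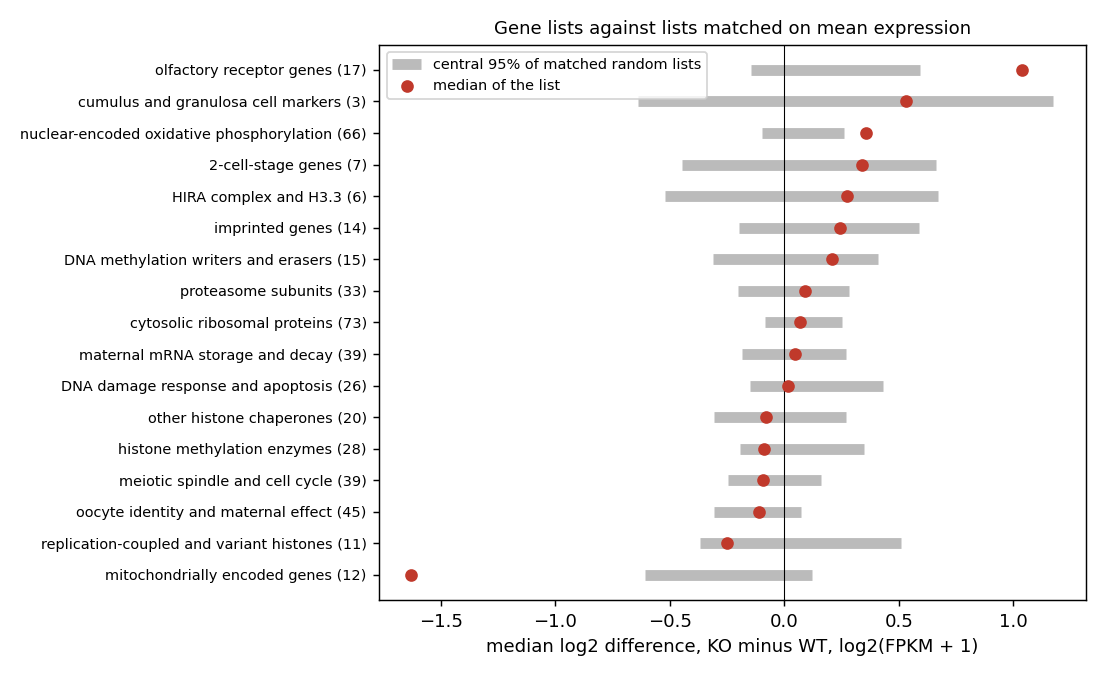
Median log2 difference of each gene list with at least 3 compared members (red points, number of members in brackets) over the central 95% of matched random lists (grey bars). The mitochondrially encoded list lies to the left of its bar, and the olfactory receptor and nuclear-encoded oxidative phosphorylation lists lie to the right of theirs.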

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

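The depth test and the tests without each library were chosen after the result was seen. In a group of 4 oocytes, a value was singled out where its gap to the nearest other exceeded Dixon's critical value for the gap over the range. This held for 19 values in 200 groups examined. The critical value gives about 1 in 20 groups by chance only where values are normally distributed. FPKM near 0 are not, as for Olfr1340 with 1 read over the WT oocytes. The number of flagged values therefore cannot be set against chance.

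WT oocyte 1 had 86.2% of its library in listed genes, against 84.4% to 84.5% in the other WT oocytes. Single WT oocytes stood above the rest for Olfr1340 (0.0244 FPKM), Cox4i2 (4.14 FPKM), Tapbpl (16.1 FPKM), Airn (0.734 FPKM) and Igkv8-26 (8.45 FPKM), and WT oocyte 1 stood below for Rps3a1 (11.5 FPKM). KO oocyte 1 stood above the other KO oocytes for Mir3473a (265.7 FPKM), Tuba3b (0.560 FPKM), S100a14 (2.09 FPKM), Airn (5.76 FPKM) and mt-Atp8 (931.9 FPKM). KO oocyte 3 stood below for ENSMUSG00000092003 (52.7 FPKM) and Npm1 (2436 FPKM) and above for ENSMUSG00000079437 (3.11 FPKM) and Aurkc (1476 FPKM). KO oocyte 5 stood above for Gm12670 (8.30 FPKM) and Ubn2 (4.01 FPKM), and KO oocyte 6 for Igkv8-26 (1.48 FPKM).

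KO oocytes had more genes detected. Depth was tested over the 16 pairs of a KO and a WT library: in 13 of them the KO library had fewer gene reads and more genes with at least 10 reads, and without each library in turn this held for 9 to 12 of 12 pairs, at or above the bound of 9, which argues against depth as the cause. RNA from other cells was tested with 68 marker genes. KO oocytes had 0.5 more of them at FPKM of at least 1 on average, and -0.17 to 1.33 without each oocyte. For the pooled markers, this argues against RNA from other cells. The lists moved in both directions. Means in WT and KO were 0.5 and 1.5 for blood and immune markers and 2.5 and 2.75 for cumulus and granulosa markers. For epithelial, stromal and endothelial markers they were 3.0 and 2.25. The pooled count cannot decide on blood and immune cells, as single lists were not tested. A difference between genotypes, between females or between library preparations stays open, as no label separates them.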

How the results depend on the processing

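Voom, cyclic loess, scaling by the share of reads in genes, thinning and leaving out mitochondrial genes were tests chosen after seeing the data. Shifts were set against 1 SD between oocytes, or for the spread measure against the SD of its values without each oocyte. For Hira, -0.17 became -0.89 with a pseudocount of 0.1 and -2.79 with voom, scales that differ by construction near 0 reads. The Hira difference was -0.59 with cyclic loess, and the cause of this shift was not tested. It was -0.23 to -0.08 without each oocyte, weakest without WT oocyte 4. Detected genes differed by 872.8, by 1279 at FPKM of at least 0.1 and 213.8 at FPKM of at least 10, where more or fewer genes qualify, by 1185.5 with at least 10 reads and 1248.5 with at least 10 reads after thinning, and by 767.6 to 995.9 without each oocyte. The share in listed genes differed by -7.56 to -5.80 percentage points without each oocyte. The difference in median SD was -0.081 to 0.027 without each oocyte, turning without WT oocyte 1. The mitochondrial median was -2.11 to -1.29 without each oocyte, lowest without KO oocyte 1. The oocyte list median was -0.25 to -0.10 without each oocyte, lowest without WT oocyte 2, -0.29 with array weights and -0.30 with voom; the cause was not tested.

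Only the numbers 1 and 5 occur in both genotypes, too few pairs to tell whether they pair oocytes: deviations from the genotype means correlated at 0.030 for number 1 and 0.068 for number 5 across genes. With a replicate block the oocyte list median was -0.40, the mitochondrial median -0.93 and the histone methylation median 0.014.

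Other signs turned by more than 1 SD for DNA damage (-0.10) and proteasome genes (-0.025) with median-of-ratios scaling, imprinted genes (-0.039) and maternal mRNA (-0.069) with quantile normalization, imprinted genes (-0.023) with cyclic loess, and histone methylation scaled by share in genes (0.018); without each oocyte the last was -0.18 to 0.044, turning without WT oocyte 4. The cause was not tested. Over named genes 1733 of 1835 values stayed within 1 SD. Leaving out 1 of 4 oocytes or changing the filter cannot move a single gene by 1 SD. This count therefore does not measure how stable the named genes are. The median of all genes was 0.10, 0.20 scaled by share in genes and -0.07 with quantile normalization. The robust prior, fry and an estimated correlation change a test and no value. Spike-in scaling and the endogenous to spike-in ratio were not run, as no ERCC values were used here.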

Other observations

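Both tests of antisense genes were chosen after the result was seen, in place of earlier ones that treated oocytes as replicates. In the FPKM as deposited, the most abundant transcripts were lower in KO oocytes and the scarce ones higher. The 48 genes with a mean FPKM of at least 1000 had a median difference of -0.62, with 37 of them below 0, and the 3508 genes under 5 FPKM a median of 0.21, with 2242 above 0. With median-of-ratios scaling the medians were -0.73 and 0.14. Quantile normalization, which forces equal distributions, gave -0.03 and -0.07, and cyclic loess, which removes trends with abundance, -0.14 and -0.05, so that with both the scarce genes were not higher.

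The 92 antisense genes compared had a median difference of 0.45, 0.22 without KO oocyte 6, and 34 were at least 2-fold higher in KO and 9 lower, against 1186 and 458 of 7054 protein-coding genes. The antisense median lay at percentile 99.99 of lists of protein-coding genes matched on mean expression. It lay above the central 95% of matched lists in 18 of 19 alternatives. It was 0.32 with quantile normalization and 0.33 with cyclic loess, where the matched ranges ended at 0.084 and 0.11. The test of abundance also required the median to stay above the central 95% without each oocyte in turn. Without KO oocyte 6 the median of the 75 genes then compared lay at percentile 95.4, within the central 95%. The position above matched lists therefore depends on KO oocyte 6. Abundance and a shift of antisense genes cannot be told apart. Medians were also high for 209 genes missing from GENCODE M21, 0.32 at percentile 99.9, and for 133 lincRNA genes, 0.28 at percentile 99.6. The genes missing from GENCODE M21 lay above the central 95% in 19 of 19 alternatives. The lincRNA genes did so in 10 of 19 and lay at percentile 94.6 without KO oocyte 6. The 44 antisense genes that share no exonic bases with another gene in GENCODE M21 had a median of 0.56, and the 48 that share some 0.26. The former was 124.4% of the median of all 92, and 81.9% to 140.0% without each oocyte. A bootstrap interval over genes, required only after the 124.4% had been seen, was -7.01% to 434.1%. With this spread, reads of overlapping exons cannot be told apart from transcription of these genes. Reads from introns on the other strand, the higher share of reads outside listed genes in KO, the genotype and the unnamed females stay open and untested.

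Mitochondrially encoded transcripts had a smaller share of gene reads in 3 KO oocytes than in any WT oocyte, and not in KO oocyte 1. Scaling of the libraries was tested with median-of-ratios, quantile and cyclic loess scaling. The median difference of the list was at most -1.17, between the bounds of -0.8 and -1.2 set before the test, so that scaling and a lower level cannot be told apart for its full size. The genotype, the unnamed females and variation between single oocytes stay open and untested.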
